A study of Homo sapiens with 4 samples.

How the data were processed

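Poly-A selected RNA from MDA-MB-231 cells was sequenced in 4 libraries, 2 from cells given DMSO and 2 from cells given the code-named compound for 24 h, with cDNA primed by random hexamers per the labels' protocols. Per the submitters' processing notes, CASAVA, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were named, with the build GRCh38; their roles, the strand setting, the annotation release and any filter are not given in the sources used here. Reads from a gene and an antisense or overlapping partner therefore cannot be told apart with certainty. The series was analysed from 1 deposited table of 26336 genes. Its column names mark a treatment and a control with numbers 1 and 2; they were taken as the compound and DMSO, since the labels hold 1 compound and 1 vehicle group.

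The per-library values are a signal that the authors deposited: read counts scaled per library, as the values show, since 100% of them were whole multiples (within 0.001) of the smallest value above 0 in their column. The smallest values were 0.997, 1.03, 0.994 and 0.964 for DMSO replicates 1 and 2 and compound replicates 1 and 2. In 2 columns this step lay so close to 1 that the check applied could not tell it from rounding, so recovered reads are not claimed and no count model was fitted. Taken as reads, the values give depths of 16042345, 15161460, 16139766 and 16497283 in the same order. The table also holds the authors' log2 fold change and the authors' p-value and adjusted p-value for each gene, per the file headers, and the group means by the authors. These were used only to be set beside the limma fit, as calls, as the values of single genes and as a correlation of fold changes. Coordinates are those of the deposited table; 99.9% of genes had the same start and end in GENCODE release 29 on the same build.

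The planned edgeR test was not used, because the deposited values are scaled and not counts, and limma on log2(value + 1) took its place, as had been laid down for that case. The plan also held a count test on recovered reads as an added alternative, which was not run, since recovered reads are not claimed. Genes with a mean value of at least 1 were tested (22486, of which 14608 protein-coding), with treatment as the only term, limma's variance moderation with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. A fold change is on the log2(value + 1) scale, which understates the change of low genes. The use of the mean-variance trend was not laid down in advance. With 2 libraries against 2 the smallest two-sided exact permutation p is 0.333, so single genes have no exact test and the limma values rest on the variance shared across genes. The GC content of each gene was taken from its longest GENCODE transcript (99.9% of genes had one). In the GC content correction a loess curve of the log2 deviation from the gene mean on GC content (span 0.3, local lines) was fitted to the 12582 genes with a mean log2 value of at least 5 and subtracted from each library; gene length was treated in the same way.

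The 44 gene lists (1011 distinct symbols), the groups, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the 44 lists. Camera compares a list with the other genes, whereas fry tests whether a list's own genes move one way or, in its mixed form, in either direction. By the rule, the text names ALKBH5, FTO and FN1, then up to 12 higher and 12 lower protein-coding genes ranked by absolute log2 fold change among those past the threshold, at 5 CPM (counts scaled to the library total) or more on average, with both compound libraries beyond both DMSO libraries, then up to 4 members with the smallest p of each list described. Lists past the threshold are described, with the m6A, AlkB, ALKBH5-linked, matrix, cell cycle, stress and cell type lists whatever they show. Genes named outside the rule, chosen after their values were seen, are METTL3, METTL14, HMOX1, PLOD1, TNC, THBS1, CD36, ACSL5, ECI1, the genes singled out for passing with the GC correction (ANXA1, CST3, EEF1A1P5, HNRNPA0, KRT7, KYNU, NTN4, SFT2D1 and SNRPG) and those changed at least 2-fold other than FABP4. A gene that passed with the GC correction alone is not reported here.

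Alternatives were a pseudocount of 0.1 or 5, no filter, a filter of 5 CPM in 2 libraries, protein-coding genes only, median-of-ratios scaling, equal totals, limma-voom, a replicate block and the removal of each library in turn. Corrections for GC content and gene length, limma without the mean-variance trend and trimmed-mean scaling (30% and 5% trims) were added after the data were seen. When a library is left out, the lone library of its group is assumed to vary like the other group.

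The fit was tested on simulated values for the same 22486 genes of the comparison of the compound with DMSO, with 50 genes changed at each fold. The changed genes were drawn from those with a mean value of at least 100, and the same assumed dispersion was set for every gene. At folds of 1.3, 1.5, 2 and 3 the fit recovered 14%, 58%, 92% and 100% of the changed genes with 0 false calls. These shares do not cover genes of lower value or a spread other than the assumed one. With a GC trend added to the simulated compound libraries, 17 unchanged genes were called without the correction and 0 with it. The corrected fit then recovered 2%, 54%, 94% and 100%. That trend was a straight line, equal in both compound libraries and absent with DMSO, which a loess curve removes by design. In the real compound libraries the highest minus the lowest GC decile was -0.14 and -0.31 (log2). The simulation therefore does not show how the correction fares on trends that differ within a group. A simulated list of 30 genes shifted by 0.25 on the log2 scale had a camera adjusted p of 1.9e-20, and 0 of 44 unchanged lists were called. These genes were simulated independently and without a GC trend, whereas the ERK feedback list, for 1, had an estimated correlation of 0.50. The simulated lists therefore do not show how often camera calls correlated lists falsely. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.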

Results

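MDA-MB-231 is an established human cell line from a triple-negative breast cancer. The cells were exposed for 24 h to the vehicle DMSO or to a compound that the labels give by a code name and that the series title calls an inhibitor of ALKBH5. ALKBH5 removes the methyl mark from N6-methyladenosine (m6A) in RNA. Polyadenylated RNA was sequenced from 2 libraries per group, and the comparison asks which transcripts differ in abundance after exposure to the compound. Taking the smallest value above 0 in each library as 1 read, the libraries held 15161460 to 16497283 reads assigned to genes. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. With the values taken as reads in the same way, the DMSO libraries differed from each other by a chi-square of 2.92 per gene. The libraries with the compound differed by 4.33. Both exceed the 1 per gene that counting error alone gives, so no pair was counted as 1 sample. This does not show that the libraries are independent cultures.

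FN1 fell with the compound. This gene encodes fibronectin, a glycoprotein of the extracellular matrix, and was followed in the published study. It was named in advance for that reason. The study may have picked it from these same libraries, so the fall of FN1 is not an independent finding. Its normalised read count was 3851 ± 161 (SD, n = 2) with DMSO and 2885 ± 383 (SD, n = 2) with the compound, a log2 fold change of -0.42 (SE 0.08; limma adjusted p = 0.0215). ALKBH5 itself stood at 1438 ± 6.09 with DMSO and 1261 ± 27.4 with the compound (SD, n = 2 each), a log2 fold change of -0.19 (SE 0.07) that missed the threshold (limma adjusted p = 0.167). FTO, the other known m6A demethylase, was at 629 ± 19.8 and 706 ± 34.3 (SD, n = 2 each; log2 fold change 0.17, SE 0.09, limma adjusted p = 0.364). In GRCh38, FN1 (ENSG00000115414) lies on the minus strand of chromosome 2 from 215360440 to 215436172. ALKBH5 (ENSG00000091542) lies on the plus strand of chromosome 17 from 18183078 to 18209954, and FTO (ENSG00000140718) on the plus strand of chromosome 16 from 53701692 to 54158512. The FN1 call was lost without any one of the 4 libraries, as was every other call, and the log2 fold change lay between -0.56 and -0.29 (limma adjusted p from 0.36 to 0.56). It was also lost, again with every other call, with limma's mean-variance trend left out, with a pseudocount of 0.1 and with no filter on low values, at a log2 fold change of -0.42 in each. Over all alternatives without a replicate block the limma adjusted p ran from 0.00072 to 0.578.

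**Figure D1:**
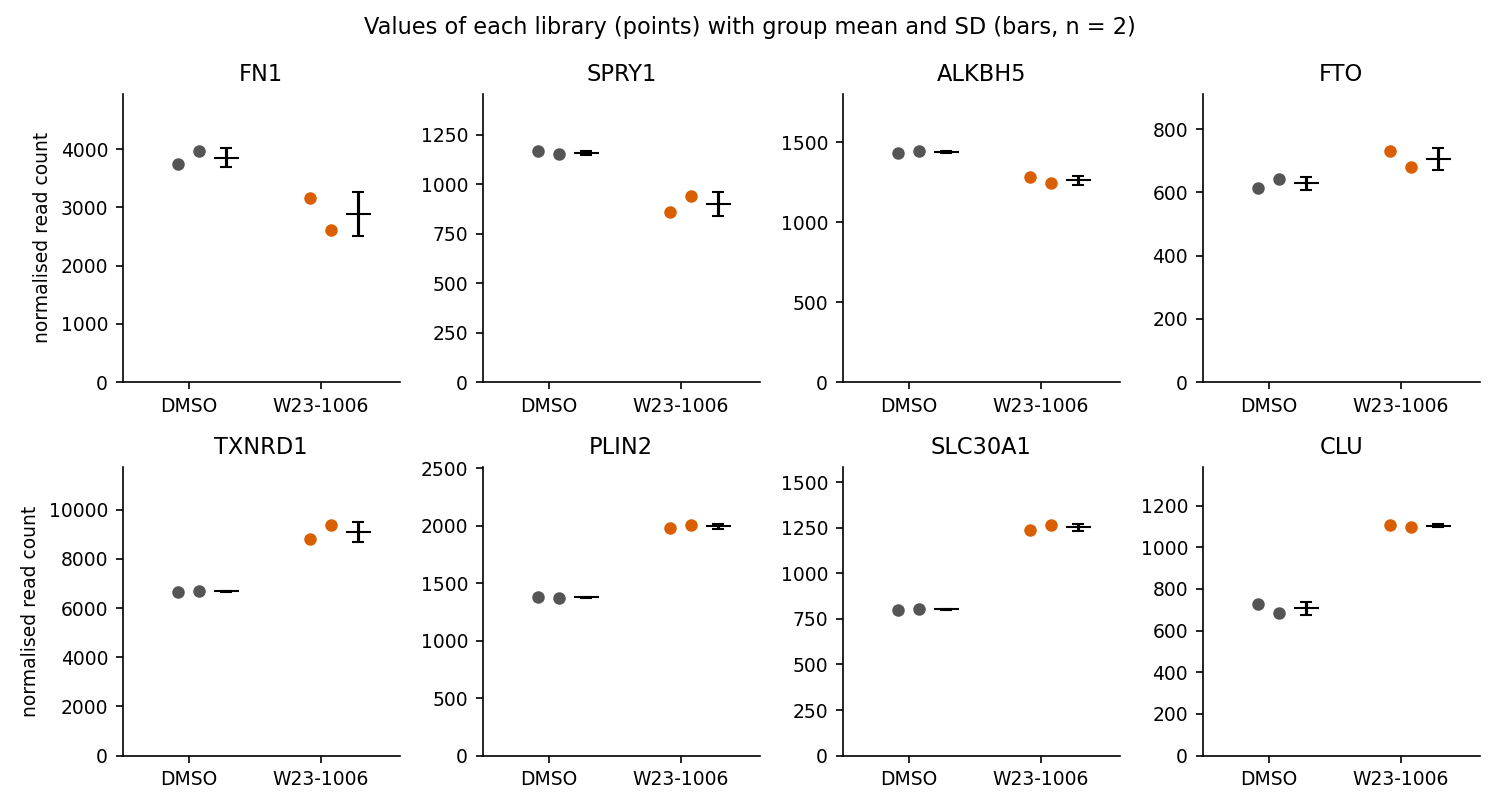
Normalised read count per library (points, y axes from 0) for 8 genes with DMSO and the compound (marked by its code name), with the group mean and SD beside them (n = 2). FN1 was 3737 and 3965 with DMSO against 3156 and 2614 with the compound, and PLIN2 was 1379 and 1375 against 1978 and 2008.

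Across 22486 genes tested, 156 rose and 328 fell with the compound (484 in all, limma adjusted p under 0.05), and most changes were small. Only 6 of these genes changed at least 2-fold. FABP4, a fatty acid carrier, rose from 53.5 ± 17.8 to 164 ± 62.3 (SD, n = 2 each; log2 fold change 1.58, SE 0.28). The other 5 were chosen after their values were seen: the lincRNA AC103718.1 rose, and LENG9, RGPD5 and the pseudogenes AC126755.1 and RPL29P11 fell. RGPD5 and the pseudogenes have near-identical copies in the genome, so their counts are uncertain. Leaving out any one library left 0 of the 484 calls (limma; 1904 to 3112 genes at an unadjusted p under 0.05), and limma with one prior variance for all genes, an alternative added after the data were seen, also called 0 (1866 at an unadjusted p under 0.05).

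The calls lay at opposite ends of transcript GC content. The median GC content was 38.6% for the genes that rose and 62.3% for those that fell, against 47.6% for the 12582 better-expressed genes. Over these genes the log2 fold change followed GC content with a Spearman rho of -0.66, a correlation across genes, which are not independent replicates. The GC-rich decile of these genes stood above the GC-poor decile, in log2 deviation from the gene mean, by 0.22 in each DMSO library, and the same difference was -0.14 and -0.31 in the libraries with the compound. After each library's GC trend was removed, a correction added after the data were seen, 21 genes passed (14 higher and 7 lower; limma adjusted p under 0.05), of which 18 had been called before in the same direction. The median log2 fold change of the 328 lower genes went from -0.40 (median SE 0.082) to -0.14 (median SE 0.076) with the correction, and that of the 156 higher genes from 0.30 (median SE 0.065) to 0.17 (median SE 0.063). Of the lower genes 306 kept their sign, and all 156 higher genes did.

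**Figure D2:**
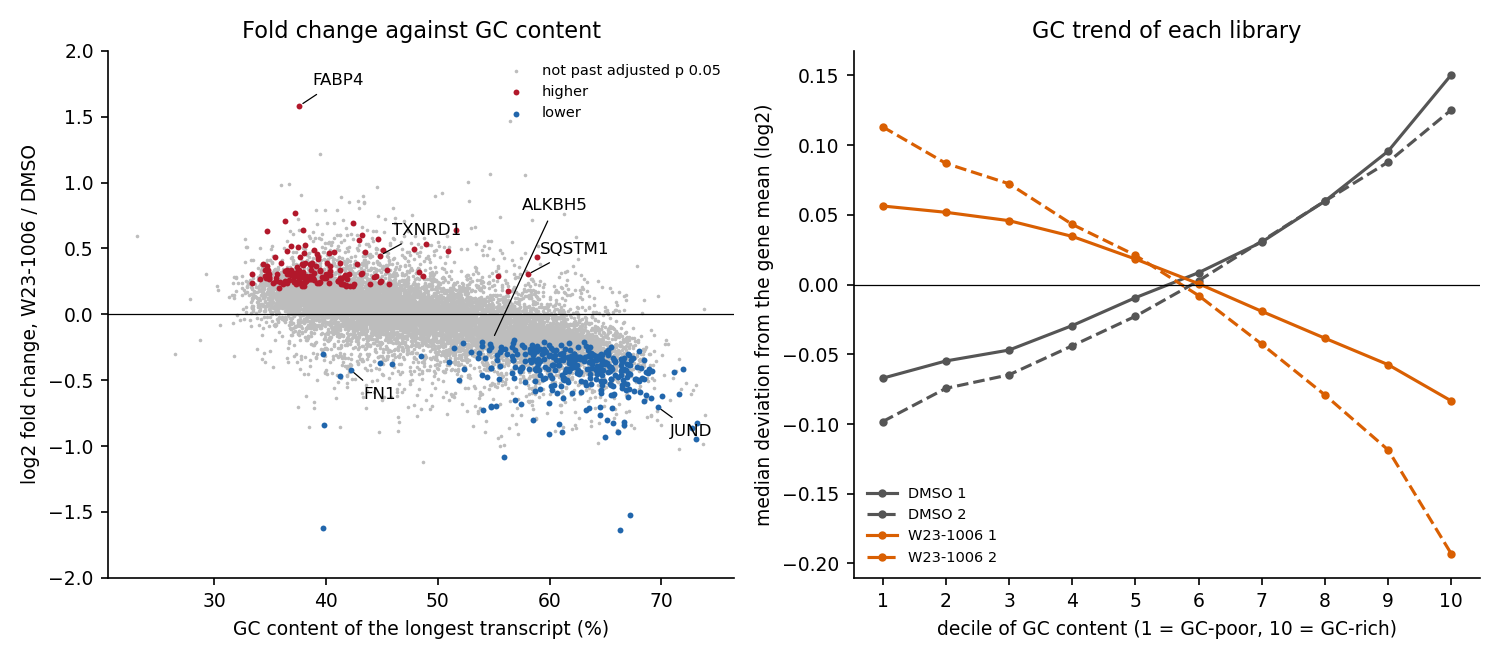
Left: log2 fold change (compound over DMSO) of 12582 better-expressed genes against the GC content of the longest transcript in percent, with genes that passed adjusted p 0.05 in red (higher) and blue (lower). Right: median log2 deviation from the gene mean in each decile of GC content for each library; the GC-rich decile is at 0.15 and 0.13 in the DMSO libraries and at -0.08 and -0.19 in the libraries with the compound.

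Of the 18 genes called with and without the GC correction, those outside the fixed rule for naming genes were chosen after their values were seen. TXNRD1, a thioredoxin reductase, rose from 6674 ± 3.33 to 9094 ± 416 (SD, n = 2 each; log2 fold change 0.45, limma adjusted p = 0.00346, and 0.39 after the correction). SQSTM1, the autophagy receptor p62, rose from 7239 ± 217 to 8926 ± 234 (SD, n = 2 each; 0.30, and 0.47 after the correction). PPP1R15A, a phosphatase subunit of the integrated stress response, rose by 0.43 on the log2 scale and by 0.61 after the correction, and FTL, the ferritin light chain, by 0.18 and by 0.31. The immediate early transcription factor EGR1 (0.29, and 0.41 after the correction), the netrin NTN4 (0.50 and 0.49), the annexin ANXA1 (0.42 and 0.29) and the kynureninase KYNU (0.48 and 0.32) rose too, as did the pseudogene EEF1A1P5 (0.32 and 0.32). FTL, SNRPG and EEF1A1P5 have close copies in the genome, so their counts are uncertain. Besides FN1, the genes that fell both ways were SPRY1, an inhibitor of receptor tyrosine kinase signalling (-0.37, and -0.42 after the correction), CST3, the secreted protease inhibitor cystatin C (-0.37 and -0.41), SFT2D1 (-0.47 and -0.57), the spliceosome protein gene SNRPG (-0.30 and -0.43) and AC126755.1.

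The 12 most changed higher genes chosen by the fixed rule spanned log2 fold changes of 0.52 to 1.58. They were led by FABP4, the zinc finger gene ZNF441 (0.77), EVI2B (0.71) and TNFSF15, a cytokine of the tumour necrosis factor family (0.69). Clusterin, the extracellular chaperone encoded by CLU, rose from 706 ± 32.8 to 1103 ± 7.43 (SD, n = 2 each; 0.64, SE 0.08, limma adjusted p = 0.00346). SLC30A1, which exports zinc from the cell, rose from 803 ± 1.87 to 1252 ± 20.6 (SD, n = 2 each; 0.64, SE 0.07), and PLIN2, a coat protein of lipid droplets, from 1377 ± 3.32 to 1993 ± 20.8 (SD, n = 2 each; 0.53, SE 0.07). The others were BIRC3, an inhibitor of apoptosis (0.63), PUS3, a pseudouridine synthase (0.60), ZNF397 (0.56), the actin-binding gene NEXN (0.52) and PTGS2, which encodes cyclooxygenase-2 (0.52). The median GC content of these 12 genes was 38.1%. After the GC correction all 12 kept their sign and 3 passed (CLU, SLC30A1 and PLIN2). FABP4 kept a log2 fold change of 1.43 (SE 0.28) and missed the threshold (limma adjusted p = 0.0723).

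The 12 most changed lower genes chosen by the fixed rule, which takes protein-coding genes above a minimum level, spanned log2 fold changes of -0.95 to -0.82. AMH, which encodes anti-Müllerian hormone, fell from 291 ± 4.31 to 151 ± 17.04 (SD, n = 2 each; -0.95, SE 0.14, limma adjusted p = 0.0107), and TERT, the catalytic subunit of telomerase, from 226 ± 0.547 to 127 ± 4.23 (SD, n = 2 each; -0.82, SE 0.15). GLI2, a transcription factor of Hedgehog signalling (-0.83), KMT5C, a histone H4 lysine methyltransferase (-0.89), MRPL23, a mitochondrial ribosomal protein gene (-0.89), PDXP, a pyridoxal phosphate phosphatase (-0.93), DLK2 (-0.91), FAM173A (-0.86), C15orf61 (-0.84), B4GALNT4 (-0.84), C4orf48 (-0.83) and RHBDL1 (-0.82) fell as well. The median GC content of these 12 genes was 65.9%. After the GC correction all 12 kept their sign, at log2 fold changes of -0.97 to -0.31, and 0 passed. AMH went to -0.43 (SE 0.13), TERT to -0.50 (SE 0.15) and DLK2 to -0.71 (SE 0.20), whereas C15orf61, with a GC content of 39.8%, went to -0.97 (SE 0.19, limma adjusted p = 0.098).

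Of the 44 gene lists tested with camera, 13 passed, 9 of them toward higher values, and 12 passed after the GC correction, 7 of them in the same direction as before. None passed with an estimated correlation in place of the preset one, before or after the GC correction, and none passed with fry in one direction, while 32 passed with fry in either direction. The estimated form of camera also rests on the few residual degrees of freedom that 4 libraries leave. Its loss of calls therefore does not show that correlation between members accounts for them. Estimated correlations differed between the lists that passed. They were 0.50 (ERK feedback), 0.45 (mitochondrial), 0.28 (ribosomal), 0.18 (glycolysis), 0.17 (zinc), 0.11 (proteasome), 0.068 (matrix) and 0.030 (repair), above the preset 0.01. The nuclear receptor, ATF4, zinc finger and iron lists were near it (0.016, 0.013, 0.011 and 0.0046). The preset lay furthest below the estimate for the ERK feedback and mitochondrial lists. The adjusted values, mostly tied, do not show this. The NRF2 targets, which defend against oxidants and electrophiles, rose with the smallest p (camera adjusted p = 1.6e-06, and 0.645 with an estimated correlation). Their estimated correlation was -0.003, under the preset 0.01, and the unadjusted camera p with it was 0.0246. Of 30 measured members 4 rose and 0 fell (7 and 1 adjusted over the list alone), 25 had a positive log2 fold change, and the mean was 0.25. TXNRD1, the cystine transporter gene SLC7A11 (0.43), TRIM16L (0.48; its reads may be shared with TRIM16) and FTL passed, and the quinone reductase gene NQO1 (0.14) and the heme oxygenase gene HMOX1 (0.23) did not. The median GC content of the list was 49.1%, and after the GC correction its mean was 0.27 with 28 members positive (camera adjusted p = 9.1e-14). TXNRD1 and FTL were the 2 members that passed after the correction (8 higher and 0 lower adjusted over the list alone), while SLC7A11, at 0.26, and TRIM16L, at 0.52, missed the threshold (limma adjusted p = 0.125 each). Without any one library its camera adjusted p lay between 1.6e-05 and 0.0125.

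The nuclear receptor and xenobiotic response list also rose (camera adjusted p = 0.000576, and 0.645 with an estimated correlation). Of its 12 members 2 rose and 0 fell (4 and 0 adjusted over the list alone), PLIN2 and FABP4. PDK4, a kinase that restrains pyruvate oxidation, stood at 0.37 and CPT1A, which carries fatty acids into mitochondria, at 0.18, short of the threshold. The median GC content of this list was 44.3%, its mean log2 fold change was 0.40 before and after the GC correction, and it passed without any one library. Iron handling genes rose as a list of 12 (camera adjusted p = 0.000691, and 0.645 with an estimated correlation; median GC content 44.4%), with FTL as the 1 member that passed (3 higher and 0 lower adjusted over the list alone) and NCOA4, the ferritin autophagy receptor, at 0.22. Of the 7 metallothionein and zinc genes SLC30A1 rose and MT2A, a metallothionein, fell (-0.21; 1 and 1 adjusted over the list alone), and the list rose (camera adjusted p = 0.0309, and 0.645 with an estimated correlation; median GC content 53.5%). The ATF4 stress list rose with 2 of 30 members, SLC7A11 and PPP1R15A (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0261, and 0.645 with an estimated correlation; median GC content 51.6%), and after the GC correction PPP1R15A alone passed and the mean went from 0.12 to 0.18 (camera adjusted p = 2.9e-08). The zinc and ATF4 lists missed the threshold without any one library (camera adjusted p from 0.0793 to 0.223), and iron handling missed it without DMSO replicate 2 (0.0868).

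Mitochondrially encoded genes, DNA repair genes, proteasome subunits and numbered zinc finger genes rose as lists as well. Of 15 mitochondrially encoded genes (median GC content 44.3%) MT-ND4L, a subunit of complex I, rose (0.31; 2 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.000576, and 0.645 with an estimated correlation). This list missed the threshold without DMSO replicate 2 (camera adjusted p = 0.314) and without compound replicate 1 (0.339). Homologous recombination and Fanconi genes rose as a list of 22 with 0 members past the threshold, also adjusted over the list alone (median GC content 40.6%; camera adjusted p = 0.00721, and 0.645 with an estimated correlation), BRCA2 standing at 0.23 and BRCA1 at 0.21. The mean log2 deviation of this list was 0.029 and -0.080 in the DMSO libraries and 0.064 and -0.013 in those with the compound, so the groups overlapped. Proteasome subunits, 31 of them measured, likewise rose as a list with 0 members past the threshold, also adjusted over the list alone (median GC content 47.5%; camera adjusted p = 0.0309, and 0.645 with an estimated correlation). Of 401 numbered zinc finger genes 5 rose and 2 fell (3 and 2 adjusted over the list alone; median GC content 43.5%; camera adjusted p = 0.0309, and 0.645 with an estimated correlation), ZNF441 rising by 0.77 and ZNF219, with a GC content of 70.1%, at -0.62. The repair list missed the threshold without DMSO replicate 2 (0.0868), the proteasome list without DMSO replicate 1 (0.0993), DMSO replicate 2 (0.26) or compound replicate 2 (0.243), and the zinc finger list without the same libraries (0.0993, 0.157 and 0.193; camera adjusted p). After the GC correction the repair, proteasome and zinc finger lists did not pass (camera adjusted p = 0.587, 0.0879 and 0.10), the mean of the repair list being -0.03 where its test pointed up, and the mitochondrial list did (0.0432). Its groups then overlapped, at mean log2 deviations of 0.033 and -0.076 with DMSO and 0.051 and -0.0082 with the compound.

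Genes of the extracellular matrix fell as a list (camera adjusted p = 0.00049, and 0.645 with an estimated correlation; median GC content 50.6%). Of 35 measured members 6 fell and 1 rose (12 and 2 adjusted over the list alone). FN1 fell together with the laminin gene LAMB3 (-0.34), the collagen gene COL13A1 (-0.37), the collagen-modifying enzymes PLOD3 (-0.37) and PLOD1 (-0.29) and tenascin C, TNC (-0.24), while thrombospondin-1, THBS1, rose (0.23). After the GC correction the list passed again (camera adjusted p = 0.0138) with a mean of -0.03 in place of -0.10. The groups then overlapped, at mean log2 deviations of 0.061 and -0.028 with DMSO and -0.041 and 0.0087 with the compound. FN1 alone of these 7 genes passed. LAMB3 had a GC content of 58.9% and went to -0.16. Without DMSO replicate 1 the list missed the threshold (camera adjusted p = 0.112).

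Glycolysis, ERK feedback and cytosolic ribosomal protein genes fell as lists and did not pass after the GC correction. Of 21 glycolysis genes 2 fell, the lactate exporter SLC16A3 (-0.33) and the aldolase ALDOC (-0.34; 6 lower and 0 higher adjusted over the list alone; median GC content 53.1%; camera adjusted p = 0.000691, and 0.645 with an estimated correlation, and 0.423 after the GC correction). Of 18 genes listed as ERK feedback genes, EPHA2 (-0.27), SPRY1 and IER3 (-0.34) fell and EGR1 rose (6 lower and 1 higher adjusted over the list alone; median GC content 50.3%; camera adjusted p = 0.00721, and 0.645 with an estimated correlation, and 0.0879 after the GC correction). Of 65 cytosolic ribosomal proteins 9 fell, led by RPL13 (-0.30), RPS15 (-0.31), RPL28 (-0.31) and RPS28 (-0.32), whose GC content was 55.3% to 60.1% against a list median of 47.9% (11 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0225, and 0.699 with an estimated correlation, and 0.0556 after the GC correction). The mean log2 deviation of the ribosomal list was 0.039 and 0.0091 in the DMSO libraries and -0.064 and 0.016 in those with the compound, which overlap. The ribosomal list pointed the other way without compound replicate 1 (camera adjusted p = 0.723) and missed the threshold without DMSO replicate 1 (0.314) or DMSO replicate 2 (0.0868). Without DMSO replicate 1 the glycolysis and ERK lists missed the threshold (camera adjusted p = 0.176 and 0.23), and so did the ERK list without DMSO replicate 2 (0.0647) or compound replicate 2 (0.197).

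**Figure D3:**
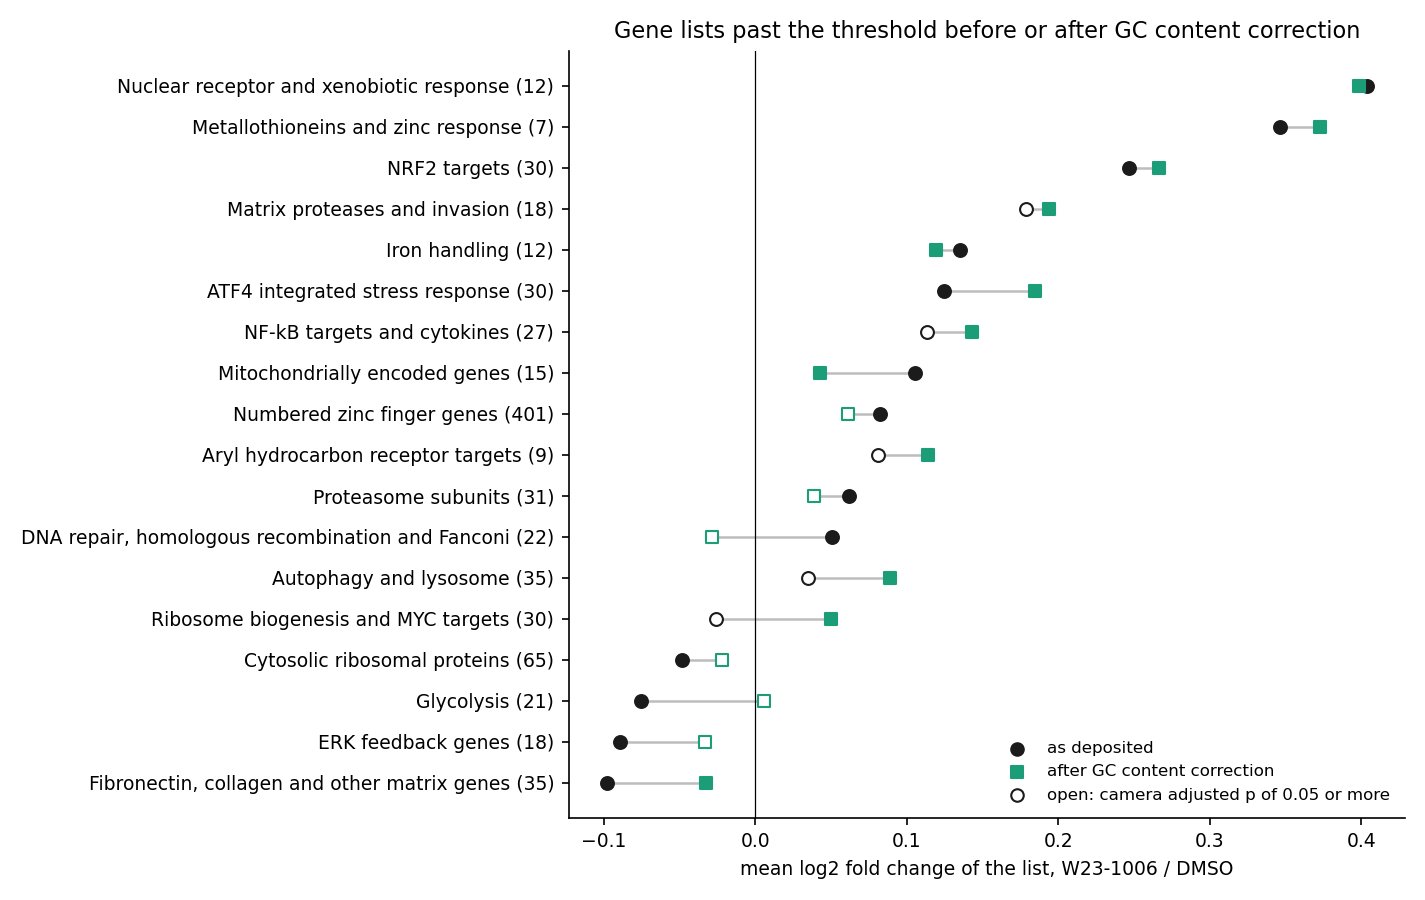
Mean log2 fold change (compound over DMSO) of each gene list that passed camera before or after the GC correction, with the number of members tested in parentheses; circles are the values as deposited, squares those after the correction, and open symbols have a camera adjusted p of 0.05 or more. NRF2 targets stayed at 0.25 and 0.27, whereas glycolysis moved from -0.08 to 0.01, where its test still pointed down.

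Of the genes that write, read and erase m6A, 1 passed the test. Of 9 writers 0 passed (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.106); METTL3, the catalytic subunit, stood at -0.08 and its partner METTL14 at 0.18. Of 13 readers PRRC2A, at a GC content of 61.7%, fell (-0.22; limma adjusted p = 0.0453) and was at 0.02 after the GC correction (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.106), and YTHDF3 stood at 0.22. Of 9 AlkB family dioxygenases, ALKBH5 and FTO included, 0 passed, also adjusted over the list alone (camera adjusted p = 0.994), the mean being -0.03 and the median 0.0027. Of 15 transcripts linked to ALKBH5 in the literature, a list that holds FN1, SLC7A11 rose (0.43) and FN1 and TRIM28, a transcriptional co-repressor, fell (-0.30 for TRIM28; 2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.444). TRIM28 had a GC content of 63.7% and was at -0.015 after the GC correction.

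The cell cycle lists did not pass camera, though both were among the 32 of 44 lists that passed with fry in either direction (adjusted p = 0.0321 for G1/S and 0.0226 for G2/M). Of 35 G1/S genes UHRF1 fell (-0.27; 0 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.531). Of 40 G2/M genes the mitotic kinase PLK1 (-0.30) and UBE2S (-0.25) fell and the kinesin CENPE rose (0.24; 3 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.444). PLK1 and UBE2S had a GC content of 57.1% and 55.7%, and CENPE of 35.3%. Of 25 p53 targets 0 passed (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.351), BAX standing at -0.32. Of 23 apoptosis regulators BIRC3 rose (2 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0866).

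The remaining stress lists did not pass camera. Of 23 heat shock genes CLU rose while the chaperone HSPA1B (-0.36) and its co-chaperone BAG3 (-0.27) fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.444). HSPA1B has a near-identical copy in the genome, so its count is uncertain. Of 23 endoplasmic reticulum chaperones and unfolded protein response genes SDF2L1, at a GC content of 65.5%, fell (-0.71; 1 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.656, mean -0.04 and median 0.0058). Of 27 hypoxia genes PFKFB4, a regulator of glycolysis, fell (-0.48; 0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.509).

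Lists of markers of other cell types did not pass camera. Of 14 luminal breast epithelial markers 0 passed (0 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0866), the keratin gene KRT8 standing at -0.23. Of 5 haematopoietic, 8 endothelial and 7 fibroblast markers 0 passed, also adjusted over each list alone (camera adjusted p = 0.796, 0.444 and 0.426), and the haematopoietic mean of 0.26 and median of -0.03 differed in sign. With DMSO, CD14 was at 8.11 ± 0.20 and COL3A1 at 5.59 ± 0.855, close to the detection floor, while COL1A1 was at 107 ± 14.8 and ROBO4 at 139.9 ± 0.85 (SD, n = 2 each). The other 11 lists did not pass (smallest camera adjusted p = 0.0866); of their 242 members tested 2 rose and 12 fell.

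The authors' deposited table lists 638 genes at an adjusted p under 0.05, 280 higher and 358 lower with the compound, and 0 of them at least 2-fold. In the authors' deposited table FN1 has a log2 fold change of -0.42 (adjusted p = 0.000284), TXNRD1 of 0.45 (3.4e-12), SLC30A1 of 0.64 (1.4e-06), PLIN2 of 0.53 (5.7e-07) and ALKBH5 of -0.19 (0.194). The log2 fold changes of its 638 calls ran from -0.79 to 0.64. By limma, all 12 lower genes chosen by the fixed rule (-0.95 to -0.82) lay beyond that range. So did FABP4 (1.58), ZNF441 (0.77), EVI2B (0.71) and TNFSF15 (0.69). Calls shared by the authors' deposited table and the limma fit numbered 392 (142 higher and 250 lower), 246 were in the table alone, and 92 were in the limma fit alone, of which 65 stand at an adjusted p of 1 in the authors' deposited table, as do 18892 of its 26336 genes. The fold changes of the authors' deposited table and of the limma fit correlated across the 12582 better-expressed genes with a Pearson r of 0.998. The median GC content was 38.9% for the higher and 61.7% for the lower genes of the authors' deposited table, and 19 of its calls passed in the same direction after the GC correction (limma adjusted p under 0.05).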

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

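The corrections for GC content and gene length, trimmed-mean scaling and limma without the mean-variance trend were chosen after the data were seen, and the cause of each difference below was not tested unless it is given. The planned DESeq2 and edgeR alternatives were not run, a departure from the plan, which allowed a count test on recovered reads. The deposited values are scaled, and recovered reads are not claimed. The 484 changed genes (156 higher, 328 lower, 6 at least 2-fold) became 0 with a pseudocount of 0.1 (3515 at an unadjusted p under 0.05), with no filter (3568), without the mean-variance trend (1866) and without any one library (1904 to 3112), where the fit had fewer samples. Changed, higher, lower and 2-fold genes numbered 770, 281, 489 and 13 with a pseudocount of 5; 1475, 637, 838 and 3 with the stricter filter and 1133, 449, 684 and 17 with protein-coding genes only, where fewer genes were tested; 820, 237, 583 and 11 with equal totals; 1192, 411, 781 and 10 with limma-voom; 774, 361, 413 and 15 with the length correction; and 21, 14, 7 and 1 with the GC correction. Median-of-ratios scaling gave the same 484 calls, and 483 of them were among the 538 under trimmed-mean scaling. A replicate block called 1731 genes (730 higher, 1001 lower, 54 at least 2-fold), but deviations of same-numbered libraries correlated at 0.04, so the numbers do not show a pairing. Calls shared with the authors' deposited table (392) numbered 0 in the settings without calls, 623 with the stricter filter, 593 with protein-coding genes, 638 with limma-voom and with the replicate block, and 19 with the GC correction. Genes of the m6A machinery past the threshold (1) numbered 4 with the stricter filter, protein-coding genes, limma-voom and the block, 2 with a pseudocount of 5, equal totals, trimmed means and length correction, and 0 with the GC correction and in the settings without calls. FN1 missed the threshold with a pseudocount of 0.1 (-0.42, limma adjusted p = 0.10), no filter (-0.42, 0.236), no mean-variance trend (-0.42, 0.578) and without any one library (-0.56 to -0.29, 0.36 to 0.56), and passed elsewhere (6.4e-10 to 0.0214). The count of 13 lists was 8 with protein-coding genes, 2 without the mean-variance trend, 4 to 12 without one library, 0 with an estimated correlation and 0 with fry. Of 66 named genes past the threshold, 10 passed again with the GC correction, 54 kept their sign without passing, and PRRC2A (0.018) and BOP1 (0.0067) turned positive. The cytosolic ribosomal list turned without compound replicate 1 (camera adjusted p over single-library removals 8.6e-05 to 0.723). The other 25 changes of sign were in values that passed in neither fit. With the GC correction they were CEBPB (0.043), SLC39A10 (-0.018), PFKL (0.019), PSMD14 (-0.014) and, by camera adjusted p, m6A readers (0.875), ALKBH5-linked transcripts (0.798), G1/S (0.927) and G2/M (0.13). G1/S turned with the length correction (0.944), and haematopoietic markers turned with no filter (0.988). The AlkB family dioxygenases turned with a pseudocount of 0.1 (0.986), no filter (0.968), equal totals (0.985), limma-voom (0.968) and no mean-variance trend (0.796), and over single-library removals (0.581 to 0.998). Single-library removals also turned the lists Endoplasmic reticulum chaperones and unfolded protein response (0.523 to 0.9996), hypoxia (0.273 to 0.974) and Ribosome biogenesis and MYC targets (0.681 to 0.881), CD79A (-1.52 to 1.06; 0.019 with a pseudocount of 5) and TIE1 (-0.15 to 2.43), whose values rest on few reads; CDH5, also low, went to 0 without compound replicate 2. In values simulated at this depth, 14% of 1.3-fold and 58% of 1.5-fold changes were recovered.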

Other observations

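The test of the library preparation against the compound, the GC and length corrections, trimmed-mean scaling and the list of further PPAR targets were chosen only after the result was seen.

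With the GC trend removed, some groups that had not passed as deposited did, all toward higher values. Autophagy and lysosome genes rose as a list of 35 with SQSTM1 past the threshold (mean log2 fold change 0.09; 3 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.000351, and 0.495 with an estimated correlation). NF-kB targets and cytokines rose as a list of 27 (mean 0.14; 3 and 0 adjusted over the list alone; camera adjusted p = 0.00625, and 0.497 with an estimated correlation) with 0 members past the threshold. BIRC3, PTGS2 and the mitochondrial superoxide dismutase gene SOD2 were higher and IER3 lower as deposited, and none of these 4 passed after the correction (limma adjusted p from 0.257 to 0.644). After the correction the groups overlapped in the mean log2 deviation of this list, at -0.20 and 0.057 with DMSO and 0.11 and 0.028 with the compound. Aryl hydrocarbon receptor targets rose as a list of 9 (mean 0.11; 0 members past the threshold, 1 and 0 adjusted over the list alone; camera adjusted p = 0.00625, and 0.538 with an estimated correlation), with CYP1B1, a xenobiotic-metabolising enzyme, at 0.38 after the correction and short of the threshold, and with overlapping groups too (0.027 and -0.14 with DMSO, 0.11 and 0.0016 with the compound). Since NQO1 is in both this list and the NRF2 targets, the rise of this list is not fully separate from theirs. Ribosome biogenesis genes rose as a list of 30 (mean 0.05; 0 members past the threshold, 1 and 0 adjusted over the list alone; camera adjusted p = 0.00372, and 0.538 with an estimated correlation), where as deposited the mean was -0.03 and the test pointed up. Matrix proteases rose as a list of 18 (mean 0.19 and median 0.048; 0 members past the threshold, 5 and 0 adjusted over the list alone; camera adjusted p = 0.03, and 0.538 with an estimated correlation). Of the proteases, as deposited, TIMP3, an inhibitor of metalloproteinases, rose (0.29) and MMP14 fell (-0.28), while MMP1 stood at 0.90 short of the threshold. As deposited these lists had, in the same order, camera adjusted p of 0.301, 0.351, 0.0946, 0.81 and 0.351. KRT7 and HNRNPA0 were among the genes that passed with the correction alone.

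Lower genes outnumbered higher ones, and the calls sorted by GC content. Removal of the GC trend left 1.83% of the lower and 7.69% of the higher calls past the threshold, and the trend may account for part of both, the median log2 fold change going from -0.40 to -0.14 and from 0.30 to 0.17. How much stays open. Of the 328 lower genes 145, and of the 156 higher genes 120, kept an unadjusted limma p under 0.05 in the same direction. These genes had been picked for a low p in the same 4 libraries, so such counts are favoured in advance. Of all 22486 tested genes 1631 had an unadjusted limma p under 0.05 after the correction, against 3752 before. Of 50 simulated genes changed 1.3-fold, the corrected fit recovered 2% with a GC trend and 20% without one. The uncorrected fit recovered 18% and 14%, each in 1 draw, so a lost call of that size shows little. Most single calls did not rest on gene length, since 296 of the lower (90.2%) and 155 of the higher calls (99.4%) stayed after its correction. That share does not measure the excess of lower genes. Among all 774 calls then made 361 were higher and 413 lower, a lower share of 53.4% against 67.8% before. Length therefore stays open as a cause of part of the excess. Lower genes made up 61.2% of all calls with trimmed means and 71.1% with equal totals (median-of-ratios scaling returned the same 484 calls and tested nothing). These rescalings moved the median log2 fold change of all tested genes only from -0.011 to -0.0049 and -0.023. Since such small shifts already moved the lower share, they cannot decide whether scaling accounts for it. Whether the GC trend came from library preparation or from the compound cannot be told apart: the smallest difference in trend between a DMSO and a library with the compound was 0.36 (log2), against 0.0059 within DMSO and 0.17 within the compound group, but the libraries of each group share a treatment and nothing in the labels separates treatment from preparation.

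The rise of the NRF2 targets and the fall of FN1 stayed when that trend was removed. After the GC correction the NRF2 list kept 108% of its mean log2 fold change and FN1 kept 122% of its own, both past the threshold, which argues against the GC trend as the whole cause of either. An oxidant or electrophile response to the compound is a candidate explanation for the NRF2 targets and an effect through ALKBH5 for FN1, but no inactive compound or ALKBH5-deficient cells were among the 4 libraries, so neither was tested. Both calls have limits in the processing: FN1 missed the threshold without any one library (log2 fold change -0.56 to -0.29), where no gene passed, and the NRF2 list missed it with an estimated correlation (adjusted p = 0.645).

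PLIN2 and FABP4 are known targets of PPAR receptors, and a wider rise of such genes may lie behind them. Of 36 other known targets, listed after PLIN2 and FABP4 had been seen, 33 were measured, 24 of them with a positive log2 fold change after the GC correction, and their mean was 0.10 (SD 0.41; camera p = 0.000687, and p = 0.111 with an estimated correlation). As deposited their mean was 0.07 (camera p = 0.00658, and p = 0.159 with an estimated correlation), with ACSL5 higher (0.25) and ECI1 lower (-0.44), neither of which passed after the correction. Both means rest on CD36, a fatty acid transporter near the detection floor (1.53 ± 0.755 with DMSO and 7.83 ± 0.166 with the compound; SD, n = 2 each), without which they were 0.05 after the correction and 0.015 as deposited. Without the genes shared with the nuclear receptor list, whose result had been seen, 30 genes remained with a mean of 0.08 after the correction (camera p = 0.0174 at the preset correlation). CD36 was still among these 30 genes, at 1.66 after the correction, so the hypothesis stays open.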
